A study of Mus musculus with 6 samples.

How the data were processed

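Messenger RNA of mouse liver was prepared as 6 sequencing libraries from total RNA of frozen tissue, per the labels' protocols. Group and replicate number were taken from the sample titles, which gave fasted 1, 3 and 4 and refed 5, 7 and 8, 3 libraries per group. The labels give each library its own sample and speak of mice, but do not say outright that each library is a separate animal, so p-values measure the spread between these samples, which may in part be technical. FastQC, STAR 2.6.0c, DESeq2 and the mouse build mm9 are named without a role in the submitters' processing notes. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are genes that share reads with close copies.

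Of the deposited tables, the first holds RPKM values on a linear scale, computed by the authors, with 1 row per RefSeq transcript and 1 column per library. Which library total the RPKM values were scaled by is not given in the sources used here. Tested on its values, the table holds 14659 transcripts, each with a maximum of at least 1 RPKM over the 6 libraries, so that transcripts low in every library were not analysed here. Its p-value column was computed by the authors without adjustment. It equals a two-sided equal-variance two-sample test on linear RPKM with a largest difference of 2.1e-13, and it was not used for any call. The other table holds the authors' calls at a false discovery rate under 0.05, with raw read counts per library as deposited, log2 fold changes of refed over fasted and p-values from DESeq, per the file headers. It has 5434 rows for 5416 distinct genes, and 9 gene names that had been turned into dates were restored from their gene identifiers. Because counts are listed for called genes alone, they were selected on the outcome. They were used for depth and for a check on repeated libraries, not for a count test, so edgeR and DESeq2 were not run as tests although the design had named them for the case of a full count table.

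Transcripts were joined to genes by RefSeq accession through a reference gene table of another build, used for names only. By accession 14390 transcripts were named, 193 by the symbol in their description and 22 by the symbol column, and 54 had no name and were left out. For 98% of those named by accession, the deposited symbol was the same or a synonym. Of 10960 genes, 2298 had more than 1 transcript, and a gene was represented by its transcript with the highest mean RPKM. Coordinates are those of the deposited gene table, with mm9 as named in the submitters' notes, and were not converted. All per-sample columns of both tables were matched to samples by name.

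Reads in the authors' called genes summed to 28542863, 30260057 and 28475836 in fasted 1, 3 and 4 and to 29464410, 33219013 and 26237934 in refed 5, 7 and 8. These sums cover part of each library, so full depth is unknown and no counting intervals are given. The reads behind 1 RPKM, relative to the mean of the libraries, ranged from 0.938 to 1.14. The 10 highest genes, led by Alb, took 20.6% to 23.2% of summed RPKM. Chi-square per degree of freedom of the counts between replicates was 59.2 to 240, so no pair of libraries repeated another within sampling noise.

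Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested, 10903 of them, and 57 were removed. Values were taken as log2(RPKM + 1), and refed was compared with fasted by limma 3.58.1 in R 4.3.3 with moderated, trended variances, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, while folds without a log are ratios of group mean RPKM. Errors of means are SD over 3 libraries, and errors of log2 fold changes are standard errors. No covariate was used, since the labels give no batch.

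Lists of genes, 35 in number, were fixed before the data were examined. They cover lipogenesis, glycolysis and fructose use, pentose phosphate pathway, gluconeogenesis, glycogen metabolism, fatty acid oxidation and ketogenesis, lipid droplet and lipolysis, cholesterol synthesis and uptake, bile acid and sterol export, lipoproteins, amino acid breakdown and urea cycle, oxidative phosphorylation, insulin and FOXO response, growth hormone and STAT5 response, circadian clock, unfolded protein response, cytosolic chaperones, immediate early genes, autophagy and lysosome, ribosome biogenesis, cell cycle, acute phase and cytokines, interferon response and xenobiotic metabolism. The rest are markers of periportal and pericentral hepatocytes, Kupffer cells, sinusoidal endothelium, stellate cells, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipocytes and pancreatic acinar cells. The 31 lists with at least 3 genes measured were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. An estimated correlation per list and fry, which does not compare a list with other genes, were run beside it. With an estimated correlation no list passed, including lists whose estimate lay near the preset. Genes were named by a rule fixed at the same time: the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 RPKM in a group, no overlap between groups and an ordinary symbol, up to 3 called members with the largest change in each list, or the 2 highest in expression where none passed, and up to 10 members of 6 lists with branches or regulators. Some genes that this rule names are not reported here. Further members named to spell out a count of 5 or fewer, and Hspa5, Scarb1, Apob, Lcat, Gls2, Gpt2 and Cyp1a2, were chosen after their values were seen. So were Saa1 and Lcn2 and the other acute phase genes given per library.

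The steps were tested on simulated data with the means and spread of these 10903 genes and 200 genes changed in each of 5 draws. Of changed genes, 33.7% were recovered at 1.5-fold, 73.9% at 2-fold and 91.5% at 4-fold, and 6% of calls were false. Adjustment is stricter where few genes change, and 4600 genes were called in the real data. The shares recovered therefore do not carry over to the real comparison. A shifted list was called in 5 of 5 draws, with 1 call of another list. The simulated noise was drawn independently for each gene. In the real data the estimated correlation within lists ranged from -0.00 for gluconeogenesis to 0.92 for Kupffer cell markers, with 0.54 for lipogenesis. The draws therefore do not show how often lists of correlated genes are called falsely. Alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 RPKM, centring on library medians, quantile normalization, TMM factors from edgeR 4.0.16, limma without a trend, robust limma, a test against an absolute log2 fold change of 0.5 (limma treat), and each library left out in turn. The mean over a gene's transcripts and counts of list members without fasted 1 were added after the data were seen. Tables were read with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.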

Results

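Messenger RNA of frozen liver from male C57BL/6J mice, an inbred laboratory strain, was sequenced in 6 libraries. The mice were 8 weeks old. The fasted group, libraries 1, 3 and 4, had a 12 h overnight fast that began at 10 pm. The refed group, libraries 5, 7 and 8, was first fasted for 12 h in the daytime and was then given a diet of 69% sucrose and 10% fat for 12 h from 10 pm. Livers of both groups were taken at 10 am, so the comparison asks how liver transcript levels differed between the fasted state and a night of sucrose feeding at a single clock hour. Expression was given as RPKM, read counts scaled by transcript length and by library total, for 14659 transcripts of 10960 named genes. Reads were listed only for the genes the authors called, and they summed to between 26237934 in refed 8 and 33219013 in refed 7.

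In refed liver, 19 of 22 genes of fatty acid synthesis, 20 of 24 of cholesterol synthesis and uptake, 17 of 19 of sugar breakdown and 16 of 24 of the unfolded protein response were higher. Lower were 24 of 28 genes of fatty acid oxidation and ketone body formation and 17 of 21 of amino acid breakdown and the urea cycle. Fasn, the fatty acid synthase, went from 19.5 ± 2.65 RPKM (SD, n = 3) in fasted to 1232 ± 283 (SD, n = 3) in refed liver, and Pck1, the gene of the cytosolic enzyme that commits oxaloacetate to glucose synthesis, went from 2084 ± 152 to 58.6 ± 49.9. Of 10903 genes tested with limma, 4600 passed a Benjamini-Hochberg adjusted p of 0.05, 2878 higher and 1722 lower in refed liver, which put 62.6% of the calls on the higher side. With each library centred on its own median, 4453 genes passed, 2186 higher and 2267 lower, and 49.1% were on the higher side. This centring moved the median log2 fold change of all tested genes from 0.10 to 0.01, and 3908 genes were called with the same sign in both fits. An absolute log2 fold change of 1 or more was found for 725 called genes, 412 higher and 313 lower.

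The groups lay apart on the first principal component of the 1000 most variable genes, which held 81.8% of their variance, with fasted libraries from -25.8 to -24.1 and refed libraries from 21.7 to 28.9. The second component, with 8.92%, placed fasted 1 at 16.2, fasted 3 at -7.86 and fasted 4 at -8.96. The median Pearson correlation across genes, which are not independent replicates, was 0.983 within fasted, 0.991 within refed and 0.945 between the groups. Fasted 1 also stood apart in acute phase transcripts, given with the immune lists. Without fasted 1, 4204 genes passed, 2561 higher and 1643 lower, and 3864 of them were among the 4600 with the same sign.

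The 8 largest rises among called genes whose groups did not overlap were those of Thrsp, Fasn, Acly, Elovl6, Chrna4, Pnpla3, Aqp8 and Pklr. Thrsp, a gene of lipogenic tissues, rose 105-fold from 23.2 ± 6.49 to 2443 ± 582 RPKM (SD, n = 3; log2 fold change 6.66 ± 0.23 SE, limma adjusted p = 2.8e-06). Acly, ATP citrate lyase, rose 46.2-fold to 1235 ± 380 RPKM (log2 fold change 5.43 ± 0.21, adjusted p = 4.1e-06), and Fasn rose 63.1-fold (5.89 ± 0.18, adjusted p = 2e-06). Elovl6, a fatty acid elongase, reached 267 ± 114 RPKM from 7.46 ± 1.64, and Pklr, the liver pyruvate kinase, 680 ± 165 from 31.6 ± 4.27. Chrna4, a nicotinic acetylcholine receptor subunit, was low in fasted liver at 0.0818 ± 0.0231 RPKM and reached 31.8 ± 12.0 in refed liver. The authors' deposited table lists 24 to 33 reads of Chrna4 in the fasted libraries and 6415 to 17406 in the refed ones. Pnpla3, a lipid droplet acyl hydrolase, went from 0.122 ± 0.0367 to 33.6 ± 18.5 RPKM, and Aqp8, a water channel, from 9.84 ± 3.81 to 242 ± 104. Because 1 was added to RPKM before taking logs, the fitted log2 fold changes of low genes are understated. For Chrna4 the fit gave 4.85 ± 0.26, and the authors' deposited table lists 8.48.

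Among the 8 largest falls were those of Pck1, Mfsd2a, Dbp, Upp2, Cpt1a, Sds and Slc7a2. Pck1 was 35.6-fold lower in refed liver (log2 fold change -5.52 ± 0.56, limma adjusted p = 0.00025). Mfsd2a, a transporter of lysophosphatidylcholine with long-chain fatty acids, went from 71.2 ± 34.7 to 2.12 ± 1.14 RPKM (SD, n = 3; -4.48 ± 0.36, adjusted p = 8.1e-05). Upp2, a uridine phosphorylase, was 12.3-fold lower. Slc7a2, a cationic amino acid transporter, was 8.31-fold lower at 14.0 ± 0.0679 RPKM. In mm9, the mouse build named in the submitters' processing notes, the deposited gene table places Fasn on chromosome 11 from 120667254 to 120685492 on the minus strand and Acly on the same chromosome from 100337667 to 100389314. It places Thrsp on chromosome 7 from 104561448 to 104566240, Pklr on chromosome 3 from 88940064 to 88950706, Pck1 on chromosome 2 from 172978549 to 172984774 and Cpt1a on chromosome 19 from 3323301 to 3385732. These intervals span whole genes, exons and introns, while RPKM was given per transcript.

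**Figure D1:**
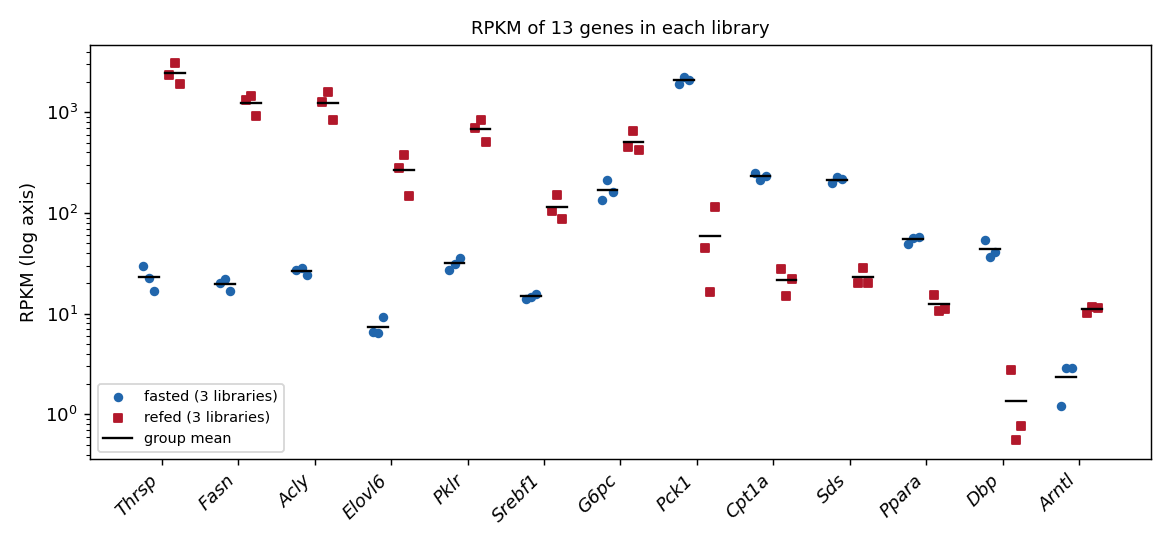
RPKM of 13 genes on a log axis in each library, with circles for the 3 fasted and squares for the 3 refed libraries and a bar at each group mean. The Fasn means are 19.5 and 1232 RPKM, those of Pck1 2084 and 58.6, and G6pc, at 169 and 509, lies higher in refed liver.

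Genes of fatty acid synthesis rose together. Of 22 measured members of the lipogenesis list, 19 were higher and 1 was lower in refed liver, and 20 passed when adjusted over the list alone (camera adjusted p = 4.3e-09, and adjusted p = 0.32 with an estimated correlation). Besides Fasn and Acly, Acaca, an acetyl-CoA carboxylase, rose 20.4-fold and Me1, malic enzyme, 10.8-fold. The regulators Srebf1 and Mlxipl were 7.7-fold and 2.77-fold higher (log2 fold changes 2.83 ± 0.18 and 1.48 ± 0.17, limma adjusted p = 3.2e-05 and 0.00042). Scd1, the stearoyl-CoA desaturase, rose from 488 ± 229 to 2975 ± 1413 RPKM (SD, n = 3). The desaturase genes of polyunsaturated fatty acids were not among those that rose. Fads2 fell by 1.20 ± 0.10 on the log2 scale (adjusted p = 0.00011). Fads1 was at 110 ± 6.29 RPKM in fasted and 109 ± 4.76 in refed liver (adjusted p = 0.97), and Elovl5 had a log2 fold change of 0.35 ± 0.25 (adjusted p = 0.28).

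Sugar-handling genes were mostly higher. Of 19 members of the glycolysis and fructose use list, 17 were higher and 1 lower, and 18 passed adjusted over the list alone (camera adjusted p = 1.3e-06, and adjusted p = 0.31 with an estimated correlation). Pklr rose 21.5-fold (log2 fold change 4.36 ± 0.18, limma adjusted p = 5.4e-06), and Tkfc, the triokinase of fructose breakdown, rose from 136 ± 17.1 to 1077 ± 127 RPKM (SD, n = 3; 2.98 ± 0.13, adjusted p = 5.8e-06). The lower member was Ldha, a lactate dehydrogenase subunit (-0.83 ± 0.15, adjusted p = 0.0038), and the member that did not pass was the fructose transporter gene Slc2a5 (adjusted p = 0.47). In the pentose phosphate pathway 5 of 8 members were higher and none lower, also 5 adjusted over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.31 with an estimated correlation). Pgd rose 14.2-fold, Rpia 9.43-fold and Tkt 2.97-fold.

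Gluconeogenesis genes went both ways. Of 13 members, 6 were lower and 3 higher, and 9 passed adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.31 with an estimated correlation). The lower genes were Pck1, Got1, Creb3l3, Gpt, Ppargc1a and Gpt2. G6pc, the catalytic subunit of glucose-6-phosphatase, was 3.01-fold higher in refed liver, at 509 ± 131 against 169 ± 39.3 RPKM (SD, n = 3; log2 fold change 1.58 ± 0.21, limma adjusted p = 0.00091), and its partner transporter Slc37a4 rose by 0.60 (adjusted p = 0.001). The other higher member, Mdh1, was past the threshold in the main scaling (adjusted p = 0.044) and in none of the other 3 scalings. The list lost its call under all 3 (camera adjusted p of 0.06, 0.12 and 0.056 for centring, quantile normalization and TMM). Of 10 glycogen genes, 5 were higher, 3 lower and 2 did not pass, and 8 passed adjusted over the list alone (camera adjusted p = 0.24), with 1 lower without fasted 1, refed 5 or refed 8. Ppp1r3b, which targets protein phosphatase 1 to glycogen, rose 3.72-fold, the phosphorylase gene Pygl 3.36-fold and the branching enzyme gene Gbe1 3.25-fold.

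Fatty acid oxidation and ketogenesis genes fell. Of 28 members, 24 were lower and none higher, and 25 passed adjusted over the list alone (camera adjusted p = 5.8e-14, and adjusted p = 0.31 with an estimated correlation). Cpt1a, the carnitine palmitoyltransferase of fatty acid entry into mitochondria, went from 231 ± 16.5 to 21.6 ± 6.4 RPKM (SD, n = 3; log2 fold change -3.40 ± 0.19, limma adjusted p = 2e-05). Ppara, the nuclear receptor of this program, fell from 54.7 ± 4.46 to 12.4 ± 2.63 RPKM (-2.07 ± 0.14, adjusted p = 4.1e-05). The thioesterase genes Acot3 and Acot1 and the cytochrome genes Cyp4a10 and Cyp4a14 were also lower, at log2 fold changes of -2.89, -2.84, -1.47 and -2.21, but each can share reads with close copies and is uncertain as a single gene. The 4 members that did not pass were Fgf21 (-0.43 ± 0.40, adjusted p = 0.43), Pdk4 (0.17 ± 0.24, adjusted p = 0.59), Acaa2 and Acadvl, of which Acadvl passed with centring and with TMM. Fgf21 passed without fasted 1, where its value was 3.46 RPKM against 9.24 and 15.3 in the other fasted libraries (-0.94 ± 0.21, adjusted p = 0.013). Among 14 lipid droplet and lipolysis genes, 8 were lower and 3 higher, with 12 past adjusted over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.31 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, fell from 73.8 ± 8.09 to 14.6 ± 0.441 RPKM, and its inhibitor gene G0s2 from 161 ± 97.7 to 27.8 ± 2.78. The higher members were Abhd5, Plin3 and Hilpda.

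Cholesterol synthesis and uptake genes rose. Of 24 measured members, 20 were higher and none lower, and 21 passed adjusted over the list alone (camera adjusted p = 4.3e-09, and adjusted p = 0.33 with an estimated correlation). Without refed 5, 19 were higher and 1 lower. Fdps, farnesyl diphosphate synthase, went from 25 ± 6.72 to 397 ± 41.1 RPKM (SD, n = 3; log2 fold change 3.96 ± 0.17, limma adjusted p = 6.9e-06), Mvd rose 9.68-fold and Lss 8.64-fold. Sqle, squalene epoxidase, rose 6.33-fold and Insig1 2.71-fold. Among the 4 members that did not pass were Srebf2 (0.27 ± 0.10, adjusted p = 0.058), Tm7sf2 and Hsd17b7. In the bile acid and sterol export list 7 of 17 members were lower and 3 higher, and 11 passed adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.31 with an estimated correlation). The transporter genes Abcg5 and Abcg8, whose products export sterols into bile, were 5.22-fold and 5.28-fold lower, and Nr0b2, a nuclear receptor regulated by bile acids, was 3.36-fold lower. The higher members were Abcb11, Akr1d1 and Slc10a1. This list lost its call with quantile normalization (camera adjusted p = 0.094). Of 17 lipoprotein genes, 3 were higher, 5 lower and 9 did not pass, and 10 passed adjusted over the list alone (camera adjusted p = 0.098), with 8 lower with TMM or without fasted 1. Angptl8, a feeding-responsive regulator of lipoprotein lipase, rose from 13.6 ± 6.22 to 211 ± 96.5 RPKM and Angptl4, another, fell from 144 ± 21.1 to 27.9 ± 12.5. Mttp and Abca1 were the other higher members, and Apoa5, Scarb1, Apob and Lcat the other lower ones.

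Amino acid breakdown and urea cycle genes fell. Of 21 members, 17 were lower and none higher, and 17 also passed adjusted over the list alone (camera adjusted p = 1e-12, and adjusted p = 0.31 with an estimated correlation). Sds, serine dehydratase, went from 215 ± 14.4 to 22.9 ± 4.53 RPKM (SD, n = 3; log2 fold change -3.19 ± 0.13, limma adjusted p = 5.4e-06). Tdo2, tryptophan dioxygenase, fell from 1320 ± 121 to 253 ± 30.0 RPKM and Oat, ornithine aminotransferase, from 569 ± 79.6 to 127 ± 26.1. Those that did not pass were Bckdhb, Nags, Otc and Prodh. Of 26 oxidative phosphorylation genes, 24 did not pass, and none passed adjusted over the list alone (camera adjusted p = 0.24). The 2 higher ones, Cox5a and Cox7a2, each at 1.17-fold, lost their calls in all 3 other scalings, and at most 1 of them passed whichever library was left out.

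**Figure D2:**
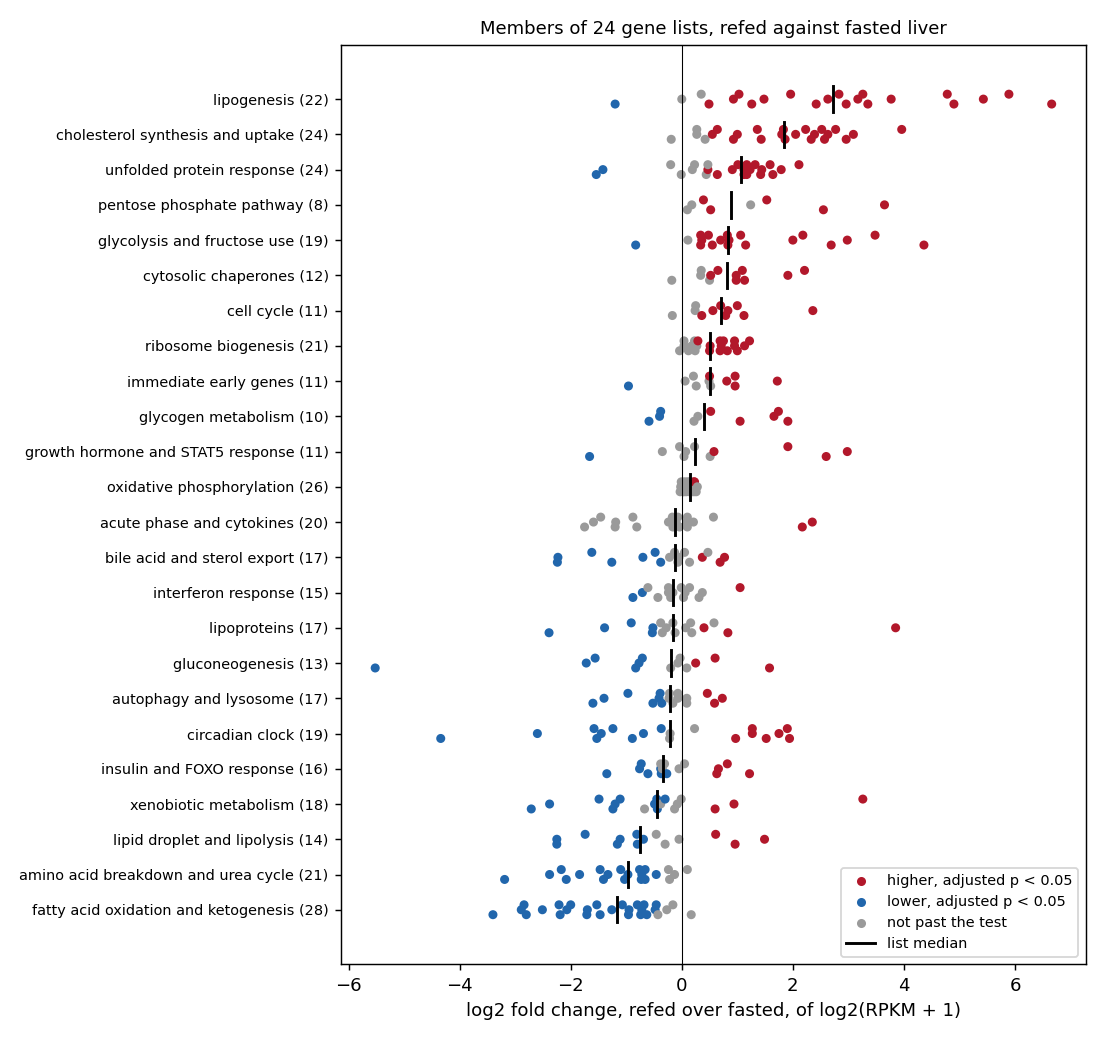
Log2 fold change, refed over fasted, of each measured member of 24 gene lists, with the number measured in parentheses, red for higher and blue for lower at an adjusted p under 0.05, grey for not past the test, and a bar at the list median. Lipogenesis lies at the top with a median of 2.73, and fatty acid oxidation and ketogenesis at the bottom with -1.17.

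Hormone-response lists were mixed. In the insulin and FOXO response list 7 of 16 members were lower and 4 higher, and 12 passed adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.31 with an estimated correlation). Klf15 fell from 95.4 ± 6.21 to 37.0 ± 3.66 RPKM (SD, n = 3; log2 fold change -1.35 ± 0.10, limma adjusted p = 5.6e-05), and Foxo1 and Insr, the insulin receptor gene, fell by 0.76 and 0.73. Gadd45a rose 3.24-fold, and Lpin1 and Pik3r1 also rose. Igfbp1, an insulin-repressed secreted protein gene, was higher in refed liver at 145 ± 7.35 against 85.3 ± 30.0 RPKM (0.82 ± 0.22, adjusted p = 0.02), and it lost its call without refed 7 or refed 8. Irs2 had a log2 fold change of -0.05 ± 0.16 (adjusted p = 0.81). The list lost its call in all 3 other scalings, at 0.099 to 0.1, without fasted 1 (0.09), without fasted 3 (0.11) and without refed 8 (0.054), and with these libraries left out in turn it held 5 higher and 5 lower, 4 higher and 3 lower, and 3 higher and 3 lower members. Of 11 growth hormone and STAT5 response genes, 4 were higher, 1 was lower and 6 did not pass, also 5 past adjusted over the list alone (camera adjusted p = 0.22). Without fasted 4, 4 were higher and 2 lower, and without refed 7, 3 were higher and 1 lower. Onecut1 rose 10.6-fold from 2.55 ± 0.459 RPKM and Cish, a STAT5-induced suppressor of cytokine signalling, 9.14-fold from 1.78 ± 0.86. Hsd3b5 and Elovl3 were the other higher members, and Bcl6 was lower (-1.66 ± 0.34, adjusted p = 0.0061).

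Clock genes changed in both directions, in livers taken at the same clock hour. Of 19 members of the circadian clock list, 9 were lower, 7 higher and 3 did not pass, and 16 also passed adjusted over the list alone. The camera test, which asks for a shared direction, gave an adjusted p of 0.22, and fry gave 0.00011 for change in either direction. Most of the other lists also passed this fry test, among them interferon response (adjusted p = 0.0044), where 12 of 15 genes did not pass singly. Dbp, a transcription factor gene of clock output, fell from 43.7 ± 8.8 to 1.36 ± 1.22 RPKM (SD, n = 3; log2 fold change -4.34 ± 0.31, limma adjusted p = 5.6e-05), and Ciart fell 12.6-fold from 9.46 ± 1.59 RPKM. Tef, Nr1d1, Per1 and Nr1d2 fell by 1.58, 1.53, 1.45 and 1.24. Arntl, the core activator Bmal1, rose from 2.33 ± 0.976 to 11.1 ± 0.858 RPKM (1.90 ± 0.21, adjusted p = 0.00039), and its relative Npas2 from 0.216 ± 0.0955 to 3.77 ± 1.23. Bhlhe40 and Per2 rose by 1.75 ± 0.12 and 1.27 ± 0.13.

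**Figure D3:**
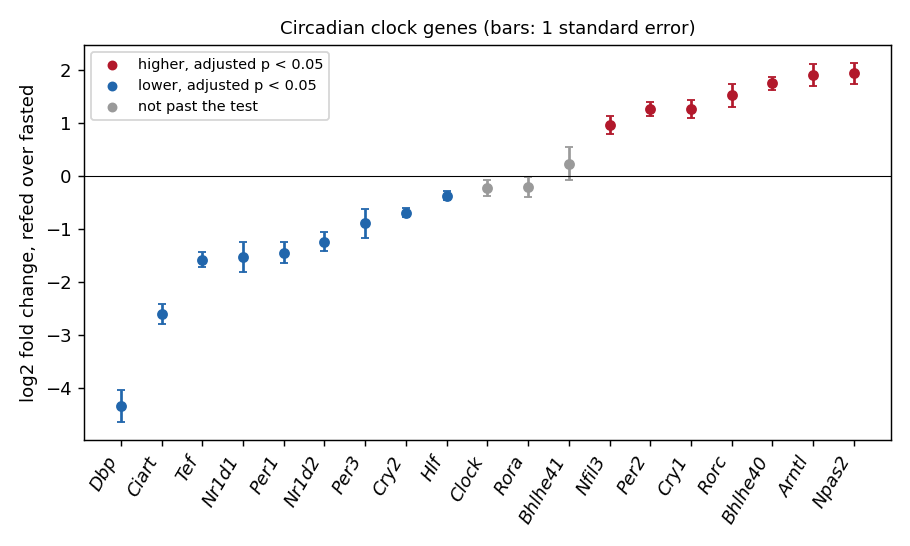
Log2 fold change, refed over fasted, of the 19 circadian clock genes, ordered by size, with bars of 1 standard error. Dbp is lowest at -4.34 and Npas2 highest at 1.94, and 9 genes are lower, 7 higher and 3 not past the test.

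Of 24 unfolded protein response members, 16 were higher and 2 lower, and 18 also passed adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.55 with an estimated correlation). Sdf2l1 rose from 14.5 ± 4.03 to 65.8 ± 13.8 RPKM (SD, n = 3; log2 fold change 2.11 ± 0.21, limma adjusted p = 0.00024), Creld2 3.69-fold and the disulfide isomerase gene Pdia6 3.13-fold. The lower members were Herpud1, a gene of the degradation branch (-1.54 ± 0.25, adjusted p = 0.0024), and Trib3 (-1.42 ± 0.18, adjusted p = 0.00067). The chaperone gene Hspa5 was at 355 RPKM in refed 7 and at 641 and 668 in the other refed libraries. Of 12 cytosolic chaperone genes, 8 were higher and none lower, and 8 also passed adjusted over the list alone (camera adjusted p = 0.0095, and adjusted p = 0.56 with an estimated correlation). Hspb1 rose 5.03-fold and Hsp90aa1 3.72-fold. Without fasted 1, 6 chaperone genes were higher (camera adjusted p = 0.018), and Hsph1 (adjusted p = 0.026 with all libraries) was among those that lost the call. The mean log2 value of this list was 4.43 in fasted 1 and 5.16 and 4.97 in the other fasted libraries. Of 11 immediate early genes, 5 were higher and 1 lower, and 6 also passed adjusted over the list alone (camera adjusted p = 0.18). The higher members were Jun, Jund, Egr1, Ier3 and Klf6 and the lower one Zfp36, with 3 higher without refed 5 or refed 8, and without refed 7 the list passed (camera adjusted p = 0.035). Of 17 autophagy and lysosome genes, 7 were lower and 3 higher, and 10 also passed adjusted over the list alone (camera adjusted p = 0.0095, and adjusted p = 0.31 with an estimated correlation). Bnip3 fell 3.14-fold, Gabarapl1 2.65-fold and Map1lc3b 2.01-fold, while Ulk1, Ctsd and Sqstm1 rose.

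In the ribosome biogenesis and cell cycle lists no gene was called lower, except 1 cell cycle gene with quantile normalization. Of 21 ribosome biogenesis genes, 13 were higher and 8 did not pass, and 14 passed adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.39 with an estimated correlation). Ppan, Nop58 and Mybbp1a rose 2.48-fold, 2.33-fold and 2.07-fold. Of 24 cell cycle genes, 11 were measured, 8 of them higher, and 8 also passed adjusted over the list alone (camera adjusted p = 0.0095, and adjusted p = 0.31 with an estimated correlation). The rest, among them Mki67, Top2a, Ccnb1, Cdk1 and Plk1, were not measured, so the counts do not speak for them. Rrm2, a ribonucleotide reductase subunit, went from 1.77 ± 0.589 to 13.2 ± 2.78 RPKM (SD, n = 3; log2 fold change 2.36 ± 0.19, limma adjusted p = 7.8e-05), and the replicative helicase genes Mcm3 and Mcm6 rose from 0.835 ± 0.283 and 0.97 ± 0.453 to 3.06 ± 1.23 and 2.89 ± 0.351. The genes Pcna, Tyms and Aurka did not pass.

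In the drug metabolism and zonation lists more genes were lower than higher. Of 18 xenobiotic metabolism genes, 10 were lower and 3 higher, and 14 passed adjusted over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.39 with an estimated correlation). Por, the reductase that supplies microsomal P450 enzymes with electrons, fell from 344 ± 37.6 to 53.2 ± 16.3 RPKM (SD, n = 3; log2 fold change -2.71 ± 0.22, limma adjusted p = 8.4e-05), and Cyp3a25 fell 5.15-fold. Gstm3 rose 10.3-fold, and Cyp2c29 and Gstm1 were the other higher members. Without fasted 1, fasted 3, refed 5 or refed 8, 6 members of this list were lower and 3 higher. Several P450 and glutathione transferase genes can share reads with close copies and are uncertain as single genes. Of 10 periportal hepatocyte markers, 6 were lower and 1, Cdh1, higher, with 7 past adjusted over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.31 with an estimated correlation). Of 12 pericentral markers, 7 were lower and 1, Glul, higher, with 9 past adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.39 with an estimated correlation). Hal and Hsd17b6 of the periportal list fell 2.82-fold and 3.05-fold. Cyp2e1 of the pericentral list fell from 5310 ± 322 to 1903 ± 252 RPKM, and Slc22a3 fell 2.79-fold. Sds, Hal and Gls2 stand in both the periportal and amino acid lists, Oat in the pericentral and amino acid lists, and Cyp2e1 and Cyp1a2 in the pericentral and xenobiotic lists. The pericentral list lost its call with quantile normalization (camera adjusted p = 0.083), and 3 of its members were lower without fasted 3 and 4 without refed 7 or refed 8. None was higher with centring, with TMM or without refed 5 or refed 8.

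Several acute phase transcripts stood out in fasted 1. Saa1 was at 6212 RPKM there and at 34.3 to 250 in the other 5 libraries, and Lcn2 was at 808 against 5.9 to 14.5. Of 20 members measured, 14 were highest in fasted 1, and 13 lay more than 1 log2 unit above the mean of the other fasted libraries. Chance gives 3.33 highest members for a library fixed in advance. Fasted 1 was singled out after its values were seen, and members move together (estimated correlation 0.66), so 3.33 is no reference for this count. Between the groups 2 members, the chemokine genes Ccl2 and Cxcl1, were higher in refed liver and 1 passed adjusted over the list alone (camera adjusted p = 0.43). The list median was -0.13 while fry gave the upward direction (adjusted p = 0.98). Cxcl1 was at 17.4, 2.65 and 33.6 RPKM in refed 5, 7 and 8 against 1.6 ± 0.152 (SD, n = 3) in fasted liver (log2 fold change 2.35 ± 0.69, limma adjusted p = 0.027). Its call was lost when any library other than refed 7 was left out, for example without fasted 1 (adjusted p = 0.064). Without fasted 1, 5 members were higher and the list passed (camera adjusted p = 0.038), while without fasted 3, fasted 4, refed 5 or refed 8 only 1 was higher. Saa1 and Saa2 can share reads as close copies. Of 15 interferon response genes, 12 did not pass. Oasl1 was higher and Rsad2 and Ifit1 lower, also 3 adjusted over the list alone (camera adjusted p = 0.24). Without fasted 3 the list passed with 1 higher and 4 lower (camera adjusted p = 0.024), and without fasted 4 it held 3 higher and 1 lower (camera adjusted p = 0.46). With the filter at 5 RPKM, 6 interferon genes remained, 2 higher and 0 lower (camera adjusted p = 0.86).

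**Figure D4:**
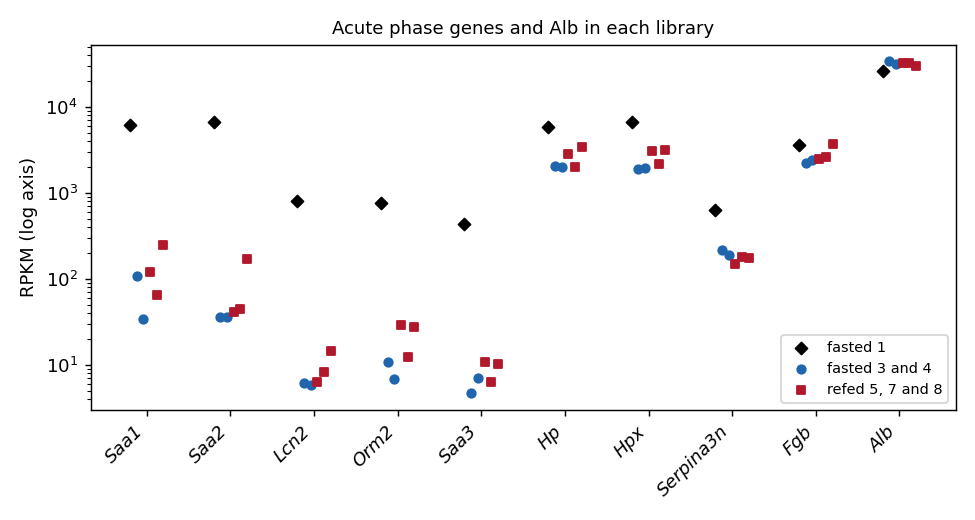
RPKM of 9 acute phase genes and Alb on a log axis in each library, with diamonds for fasted 1, circles for fasted 3 and 4 and squares for the 3 refed libraries. Saa1 is at 6212 RPKM in fasted 1 and at 34.3 to 250 elsewhere, while Alb lies between 26029 and 33984.

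Few markers of other liver cell types passed the test. None of 10 Kupffer cell markers passed, also 0 adjusted over the list alone and with camera adjusted p = 0.8, and at an unadjusted p under 0.05 the count was 0 as well. The Kupffer median was 0.08 while camera gave the downward direction. Of 10 sinusoidal endothelium markers, Cdh5 and Oit3 were higher, at 1.58-fold and 1.55-fold, also 2 adjusted over the list alone (camera adjusted p = 0.29). Of 10 stellate cell markers 1, Des, was higher at 1.63-fold (adjusted p = 0.046) and 0 adjusted over the list alone (camera adjusted p = 0.42), and Des lost its call in all 3 other scalings. Without fasted 4, 3 stellate markers were higher (camera adjusted p = 0.09), and none without any other library. Of 6 cholangiocyte markers, Krt19, Sox9 and Krt7 were higher, also 3 adjusted over the list alone (camera adjusted p = 0.33), each under 3 RPKM in both groups, and Krt7 lost its call with centring and with quantile normalization. None of 6 erythroid genes passed, also 0 adjusted over the list alone (camera adjusted p = 0.85), and at an unadjusted p under 0.05 the count was again 0. Without fasted 1, 5 erythroid genes were higher (camera adjusted p = 0.016), as were 2 Kupffer markers (camera adjusted p = 0.059) and 4 sinusoidal endothelium markers (camera adjusted p = 0.09). The mean log2 value of the erythroid list was 4.06 in fasted 1, 2.88 and 2.71 in the other fasted and 3.33 to 3.53 in the refed libraries, and that of the Kupffer list was 3.75, 2.43 and 2.96 and 3.04 to 3.16. The globin genes can share reads as close copies. Of the neutrophil list S100a8 and S100a9 were measured, at 0.954 ± 1.46 and 0.586 ± 0.539 RPKM (SD, n = 3) in fasted liver, and neither passed, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, but S100a8 was higher without fasted 1 (1.05 ± 0.30, adjusted p = 0.032). Of the adipocyte list Adrb3 and Cfd were measured and neither passed, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Cfd was lower without fasted 1 (-0.56 ± 0.15, adjusted p = 0.026) and with quantile normalization (adjusted p = 0.039), and Adrb3 without refed 7 (adjusted p = 0.049). Of 2 pancreatic acinar genes Cela1 was higher at 1.63-fold, also 1 adjusted over the list alone. No lymphocyte marker was among the genes tested.

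The authors' deposited table of calls, made from the same libraries and so not independent, lists 5434 rows, 2549 higher and 2885 lower in refed liver. Of its genes, 4388 were tested here and 3601 of them, 82.1%, were called here too, 3593 with the same sign. Across genes in both tables the log2 fold changes correlated with a Pearson r of 0.95 and a Spearman rho of 0.96, and those fitted here were higher by a median of 0.12. Of the 999 genes called here only, 924 were higher in refed liver, and of the 787 called in the authors' deposited table only, 704 were lower. This mismatch depends in part on the scaling. With centring, quantile normalization and TMM factors fewer genes were called here, but 3910, 3878 and 3952 of them were in the authors' deposited table. For the genes named most often, that table lists log2 fold changes of 5.85 for Fasn, 6.49 for Thrsp, -5.26 for Pck1, -3.52 for Cpt1a, 1.46 for G6pc and -5.18 for Dbp.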

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

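The mean over transcripts and the list counts without fasted 1 were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the groups share no replicate number. The planned DESeq2 test was not run, since counts are listed for genes the authors called and for no others. The count of called genes, 4600, was 4453 to 4611 under the other pseudocount, no filter, the scalings, the variance models and the mean over transcripts, and 3221 of 6424 genes with the filter at 5 RPKM. It was 3444 to 4204 with a library left out, lowest without refed 5. Against an absolute log2 fold change of 0.5, a stricter question by construction, 742 genes passed, 416 higher and 326 lower, and 716 of them were in the authors' deposited table in place of 3601. With a pseudocount of 0.1, 1130 called genes in place of 725 had an absolute log2 fold change of 1 or more, since that pseudocount shrinks low genes less. The split of calls moved from 62.6% higher to 49.1%, 48.6% and 48.1% with centring, quantile normalization and TMM factors.

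With an estimated correlation 0 lists passed with camera in place of 18, and 1, amino acid breakdown and urea cycle, had an unadjusted p under 0.05 (0.014). Lists with an estimate near the preset lost their calls too. Insulin and FOXO response, estimated at 0.01, went from a camera adjusted p of 0.041 to 0.31. Gluconeogenesis, estimated at -0.00, went from 0.031 to 0.31. Correlation between genes thus does not alone account for the lost calls of these lists. Of 463 list values under alternatives, 411 kept direction and side of the threshold, 35 lost the call and 7 gained it in the same direction, and 10, from 5 lists, changed direction. None of those 10 was called in the reported analysis. The acute phase list, downward at 0.43, turned upward with quantile normalization (0.91), with fry (0.98), without refed 7 (0.95) and without fasted 1, where it was called (0.038). The Kupffer list turned upward with fry (0.88) and without fasted 1 (0.059, and up to 0.91 with another library left out), and the interferon list upward at 5 RPKM (0.86). The stellate list turned downward without fasted 3 (0.96, lowest 0.09 without fasted 4), and the erythroid list downward without fasted 3 or 4 (0.96 and 0.48, with 0.016 to 0.97 over all libraries left out). With the filter at 5 RPKM the lists gluconeogenesis, insulin and FOXO response, cell cycle and pericentral hepatocyte lost their calls, at camera adjusted p of 0.1, 0.11, 0.11 and 0.11. That filter left them 11, 11, 3 and 9 genes in place of 13, 16, 11 and 12, and the cause was not tested further. With fry the cytosolic chaperone and xenobiotic lists missed the threshold, at 0.067 and 0.081, and glycogen, growth hormone, sinusoidal endothelium and cholangiocyte passed it. The median Pearson correlation between libraries fell from 0.983 to 0.978 within fasted and from 0.945 to 0.912 between groups at a mean of at least 5 RPKM, and the cause was not tested. Of 3154 values of 199 named genes, 2974 kept direction and side of the threshold, 137 lost the call, 22 gained it and 21, from 11 genes, changed sign, none of them called in either analysis. Under centring, quantile normalization and TMM the log2 fold change of Enho was -0.04, -0.04 and -0.05 in place of 0.05, and with centring and TMM that of Pcx was -0.00 and -0.03 in place of 0.09. With a library left out the log2 fold changes that changed sign ranged from -0.25 to 0.54 for Enho, -0.04 to 0.17 for Pcx, -0.13 to 0.34 for Pdk4, -0.21 to 0.50 for C1qc and -0.12 to 0.53 for C1qa. They ranged from -0.05 to 0.03 for Fads1, -0.23 to 0.10 for Irs2, -0.05 to 0.25 for Alas2, -0.09 to 0.01 for Pck2, -0.16 to 0.02 for Gpd1 and -0.04 to 0.57 for Bhlhe41. Under the 3 other scalings Cox5a, Cox7a2, Des, Mdh1 and Msmo1 lost their calls. Full depth is unknown. The simulated draws recovered 33.7% of 1.5-fold changes, but 200 of 10903 genes were changed in them, while 4600 were called in the real data. Adjustment is stricter where few genes change, so this share does not carry over to the real comparison. Small changes can still be missed, at a rate that was not measured.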

Other observations

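The families in this and the next paragraph, the test of fasted 1 against a refed origin and the test of clock genes in 2 arms were chosen after the data were seen. The camera p-values of the families are therefore descriptive and cannot test whether a family changed. Tubulin genes rose in refed liver. Of 11 measured, 9 were higher and none lower, with a median log2 fold change of 1.35 (camera adjusted p = 5.5e-05 over the 11 families, and adjusted p = 0.31 with an estimated correlation). Tubb2a went from 11.8 ± 4.52 to 171 ± 10.3 RPKM (SD, n = 3; log2 fold change 3.82 ± 0.25, limma adjusted p = 3.8e-05) and Tubb5 from 13 ± 1.33 to 44.1 ± 2.75. Close tubulin copies can share reads and are uncertain as single genes. Of 35 actin cytoskeleton genes, 17 were higher and 1, Capza2, lower (camera adjusted p = 0.00092, and adjusted p = 0.39 with an estimated correlation), and Actb, often used as a reference gene, went from 187 ± 25 to 500 ± 50.7 RPKM. Gapdh, of the glycolysis list and another frequent reference gene, went from 83.9 ± 4.73 to 176 ± 16.2. Both passed under the 3 other scalings, at log2 fold changes of 1.31 to 1.52 for Actb and 0.95 to 0.99 for Gapdh. The tubulin counts were 9 higher and 0 lower under each of those scalings and with any library left out. Of the actin cytoskeleton genes 14 to 15 were higher and 2 to 3 lower under those scalings, and 13 to 19 higher and 0 to 1 lower with a library left out.

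Of 20 aminoacyl-tRNA synthetase genes 18 were higher and none lower (camera adjusted p = 6.8e-06, and adjusted p = 0.31 with an estimated correlation), with Tars rising from 41.9 ± 5.49 to 161 ± 21.6 RPKM (SD, n = 3; log2 fold change 1.92 ± 0.13, limma adjusted p = 4.2e-05). Of 37 proteasome genes 23 were higher and 1, Psmd9, lower (camera adjusted p = 0.00019, and adjusted p = 0.4 with an estimated correlation), with 18 to 19 higher under the other scalings and 15 to 25 with a library left out. Of 39 genes of vesicle coat II, the signal recognition particle and the translocon 23 were higher and 4, Sec22c, Sec23a, Sec16b and Sec16a, lower (camera adjusted p = 0.0037, and adjusted p = 0.39 with an estimated correlation), with 17 to 18 higher under the other scalings and 17 to 22 with a library left out. Of 80 genes of cytosolic ribosomal proteins and their paralogs 37 were higher with a median of 0.29 (camera adjusted p = 1.6e-05, and adjusted p = 0.4 with an estimated correlation), with 15 to 29 higher under the other scalings and 13 to 55 with a library left out. In the mitochondrial carrier family Slc25 more genes were lower than higher, with 18 of 37 lower and 6 higher (camera adjusted p = 0.00015, and adjusted p = 0.22 with an estimated correlation), led by Slc25a34 at 6.26 ± 0.401 against 0.515 ± 0.165 RPKM. Acyl-CoA thioesterase genes were lower for 6 of 10 and higher for 3, Acot7, Acot9 and Acot11 (camera adjusted p = 0.014, and adjusted p = 0.39 with an estimated correlation), and 4 of the lower ones belong to the fatty acid oxidation list. Of 18 UDP-glucuronosyltransferase genes 3 were lower, 5 to 14 under the other scalings and 1 to 3 with a library left out (camera adjusted p = 0.00047, and adjusted p = 0.39 with an estimated correlation), and close copies can share reads. Ugt1a10, Ugt1a2 and Ugt1a7c were near-equal, at 180, 182 and 177 RPKM in fasted and 159, 160 and 156 in refed liver. These counts and the camera test may thus weigh the same reads more than once. Of all 10903 genes tested, 1722 were lower, beside 3 of these 18. Peroxin genes, 2 higher and 5 lower of 16, and F-box genes, 4 higher and 4 lower of 21, had a camera adjusted p of 0.099 and 0.36. The peroxin counts were 1 higher and 6 lower under each other scaling, and 1 to 4 higher and 4 to 5 lower with a library left out. No median of a family with a camera adjusted p under 0.05 changed sign under the other scalings.

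More genes were called higher than lower in refed liver, 2878 against 1722. Low genes as the whole cause are argued against by the 61.5% of calls that were higher among genes with a mean of at least 5 RPKM. The share was 49.1% once each library was centred on its median, but centring itself puts the median change near 0 and the share near 50%, so this decides nothing. Because RPKM is scaled by a library total, an equal rise of all transcripts with feeding would not show in it. A rise of most transcripts relative to the rest with feeding, the difference the design names, would show. It cannot be told apart here from an offset between libraries left by the RPKM scaling, since either shifts most genes of a group in 1 direction.

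Acute phase transcripts were high in fasted 1, with Saa2 at 6664 RPKM against 35.9 to 171 in the other 5 libraries. A refed liver under the label of fasted 1 is argued against by its place on the lipogenesis list, -0.05 where 0 is the mean of the other fasted libraries and 1 the refed mean. Neutrophils as the source of Lcn2 are argued against by S100a8, the higher of the 2 neutrophil genes measured, at 2.63 RPKM and a ratio to Lcn2 of 0.0033. Kupffer cell markers had a list mean of 3.75 log2 units there against 2.43 and 2.96 in the other fasted libraries, and cells of that type as the source were not tested. The design has no group that bears on this library, so no difference between animals was tested as an explanation.

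Clock genes were called in opposite directions, 9 lower and 7 higher. An offset between libraries is argued against by at least 7 clock genes called in each direction under every other scaling, and a single library as the cause by at least 7 in each direction whichever library was left out. Whether genes peaking with Arntl and genes of its output moved apart stays open, because these arms were drawn up after the directions were seen and the exact two-sided permutation p of 0.0077 over all 18564 assignments uses the same genes. The mean log2 fold change was 1.23 (SD 0.80) over 6 genes that peak with Arntl, 5 of them above 0, and -0.95 (SD 1.63) over 12 output genes, 3 of them above 0, and genes are not independent. The groups differed in the time of day of the fast, in feeding and in diet together, so whether the timing of food, its presence or its sugar content may set these directions stays open and was not tested.

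The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1 of 10 splits with as many genes, 4600, and the highest other split gave 0 with limma (up to 231 at an unadjusted p under 0.05, against 5539). For lists it was also 1 of 10, with 18 lists in the real split and 11 to 16 in the others. Every other split puts fasted and refed libraries in the same group. The difference between fasted and refed then widens the spread within groups, which leaves few gene calls, and also remains in part between them. Neither count is therefore a reference for the absence of a difference.

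Mt1, a metallothionein gene, was at 1021 RPKM in fasted 1 and at 52 to 218 in the other libraries. The third principal component, which held 4.02% of the variance, set refed 7 at 9.47 against refed 8 at -9.24, with refed 5 between them at -1.60. Of genes called both here and in the authors' deposited table, 8 had opposite signs, among them Cyb561a3, at a log2 fold change of -0.37 here and 2.69 in that table.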
